A study of Arabidopsis thaliana with 7 samples.

How the data were processed

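Total RNA from whole Arabidopsis thaliana seedlings was measured on 7 one-colour arrays with a biotin label, 1 array per sample. The seedlings were 7 days old and had been grown at 21 °C in long days of 16 h light and 8 h dark, per the labels' protocols. The groups were Col (the Columbia wild type, 3 arrays), soc1-101D (an early-flowering gain-of-function mutant of SOC1 in the Col background, 3 arrays) and soc1-2 (a late-flowering loss-of-function mutant, 1 array). The labels number the experiments 1, 2 and 3. Col and soc1-101D have an array in each, and soc1-2 has an array in experiment 3.

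The deposited table holds 1 intensity per probe set and array on a linear scale, and the software that made these values is not given in the sources used here. The 2% trimmed mean of the deposited intensity ranged from 495.5 to 496.2 over the 7 arrays, as after scaling of whole arrays to a common target. Medians ranged from 178.75 in soc1-101D of experiment 3 to 206.8 in soc1-101D of experiment 1. Each array held 22746 probe sets once the control probe sets (names starting with AFFX) were left out, and the number of arrays limits the precision of each value.

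Each array was scaled to the common median of 192.7, the geometric mean of the 7 medians. A pseudocount of 19.3, which is 0.1 times that median, was added before taking log2. A fold change is therefore on the log2(signal + pseudocount) scale and understates the change of dim genes. The 40% of probe sets with the lowest mean log2 value over the 7 arrays were left out, which left 13648. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the genotype and the experiment number as fixed terms. P-values were adjusted by the Benjamini-Hochberg method over the 13648 probe sets, and an adjusted p under 0.05 was called. The fit left 2 residual degrees of freedom, and the variance prior added 5.62. The soc1-2 coefficient takes its spread from the Col and soc1-101D pairs, so the lone array is assumed to vary like the others. It also draws on the soc1-101D array of experiment 3, which helps to set the level of that experiment. Beside this fitted coefficient, the plain difference from Col within experiment 3 is given with no p.

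The experiment number was kept as a block because each description in the labels names the Col array of the same experiment as the baseline. In a check of the pairing, deviations from the group mean correlated between the Col and soc1-101D arrays of 1 experiment at r = 0.85, 0.74 and 0.82 across probe sets. Each of the 6 arrays correlated best with the other array of its own experiment. The labels do not say that the experiments came from separate plantings, so p-values measure the spread between these samples, which may be technical.

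Gene names came from a table that pairs probe sets with platform annotation. It gave 1 gene for 13513 probe sets, several for 503 and none for 8730, which are unnamed here. For 13484 probe sets the symbol was updated through a RefSeq gene table of the assembly TAIR10.1, used for names and for which genes neighbour each other. Of the 13648 tested probe sets, 7276 had 1 gene. No genome build is named for the arrays, and positions are not given.

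The groups, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined, except the alternatives and tests that the closing parts give as chosen later. The rule took the 10 called named genes with the largest rise and the 10 with the largest fall in soc1-101D, with the same sign in all 3 experiments. It also took up to 6 members of each list by p in soc1-101D and up to 3 by size in soc1-2, the 10 highest and 10 lowest differences on the soc1-2 array, and the 10 largest differences of opposite sign in the 2 mutants. Together these were 73 genes. The 18 lists held 266 genes, of which 45 were named on the array and 29 were tested. They covered flowering time, floral meristem and organ identity, the cold regulon, abscisic acid and drought, the circadian clock, photosynthesis, gibberellin, salicylate defence, jasmonate and wounding, glucosinolate, anthocyanin, heat shock, touch and handling, the cell cycle, the shoot meristem, root markers, seed storage markers and the neighbours of SOC1 by locus number. The 6 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. List medians were also ranked among 10000 random lists matched on mean signal. A further grouping by symbol prefix was added after the data had been seen.

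The steps were tested on simulated data with 200 of 13648 probe sets changed, in 5 simulations. For soc1-101D against Col, 65% of the 2-fold changes and 99.6% of the 4-fold changes were recovered, and 5.4% of the calls were false. For the lone soc1-2 array the recovered shares were 4% and 86%, with 4.46% false calls. The list test found 5 of 5 simulated lists of 10 members shifted by a log2 of 0.8, and called 0 unshifted ones, in the soc1-101D comparison. The tested lists held 3 to 8 members, and lists that short were not simulated. The alternatives were a fit without the experiment block, experiment as a random effect, the deposited scaling, quantile normalization, other filters and pseudocounts, a variance trend with a robust prior, other thresholds, and each experiment left out in turn.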

Results

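SOC1 encodes a MADS-box transcription factor that promotes flowering. Transcript levels were compared in 7-day-old seedlings of the Col wild type, the gain-of-function mutant soc1-101D and the loss-of-function mutant soc1-2, to find genes that act downstream of SOC1. There were 3 Col arrays, 3 soc1-101D arrays and 1 soc1-2 array. Arrays of the same experiment correlated at r = 0.954 to 0.983 across probe sets, and arrays of different experiments at r = 0.824 to 0.929. The gene table used here paired no probe set with SOC1 (AT2G45660), so the level of the targeted gene was not checked by name and the genotypes rest on the labels.

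The first comparison asked which genes differed when SOC1 was overactive. In soc1-101D seedlings 37 probe sets rose and 37 fell against Col of the same experiment, and all 74 moved the same way in all 3 experiments (limma, adjusted p under 0.05, 13648 tested). Of these, 15 that rose and 19 that fell had 1 gene name. The floral repressor gene SMZ (AT3G54990), which encodes an AP2-type transcription factor, was 2.86-fold lower (log2 difference −1.52 ± 0.20, limma SE, limma adjusted p = 0.0279). For log2 differences of genes, ± gives the SE of the limma fit, whose variance is drawn toward the prior. It understates the observed spread of genes that vary widely between pairs. The 3 differences of SMZ had an SD of 0.48. Its scaled signal was 374 ± 190 in Col and 112 ± 37.2 in soc1-101D (SD, 3 arrays each). SMZ did not pass with quantile normalization (adjusted p = 0.0827), without experiment 1 (0.0903), with no filter on dim probe sets (0.479) or without the experiment block (range over the alternatives 0.00986 to 1.00).

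The named genes with the largest rises included cytochrome P450 and chitinase genes. CYP71B22 (AT3G26200) was 3.46-fold higher (log2 1.79 ± 0.14, limma adjusted p = 0.00592), with a signal of 78.8 ± 13.4 in Col and 322 ± 61.7 in soc1-101D. CYP71B24 (AT3G26230) was 2.83-fold higher (log2 1.5 ± 0.15, limma adjusted p = 0.0113). The chitinase gene CHI (AT2G43570) was 3.35-fold higher (log2 1.74 ± 0.19, limma adjusted p = 0.0148), from 257 ± 138 in Col to 951 ± 516. AT5G52810, whose product acts in the synthesis of the immune signal pipecolic acid, was 2.46-fold higher (log2 1.3 ± 0.17). AT5G39670, AT1G65500, AT5G24210, AT1G64360, AT2G25735 and AT5G22460 rose by log2 differences of 1.57, 1.47, 1.43, 1.40, 1.36 and 1.29, with limma adjusted p between 0.00954 and 0.0357.

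Among the named genes that fell, 2 encode proteins with a TRAF-like domain. AT4G01390 was lower by a log2 of −2.87 ± 0.32 (limma adjusted p = 0.0162), a size that depends on the pseudocount, since its soc1-101D signal of experiment 3 was 7.65, and AT3G28220 was 6.33-fold lower (log2 −2.66 ± 0.20, limma adjusted p = 0.00592). The signal of AT3G28220 was 2392 ± 1701 in Col and 331 ± 248 in soc1-101D. The lectin gene AT1G52000 was 3.63-fold lower (log2 −1.86 ± 0.19), and AT2G29340 was 2.90-fold lower (log2 −1.54 ± 0.15), both with limma adjusted p = 0.0113. TPS-CIN, which encodes a 1,8-cineole synthase, differed by a log2 of −1.23 ± 0.17, and MSRB6, which encodes a methionine sulfoxide reductase, by −1.15 ± 0.17. AT1G21670, AT1G56310 and AT4G27450 had log2 differences of −1.35, −1.23 and −1.23.

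**Figure D1:**
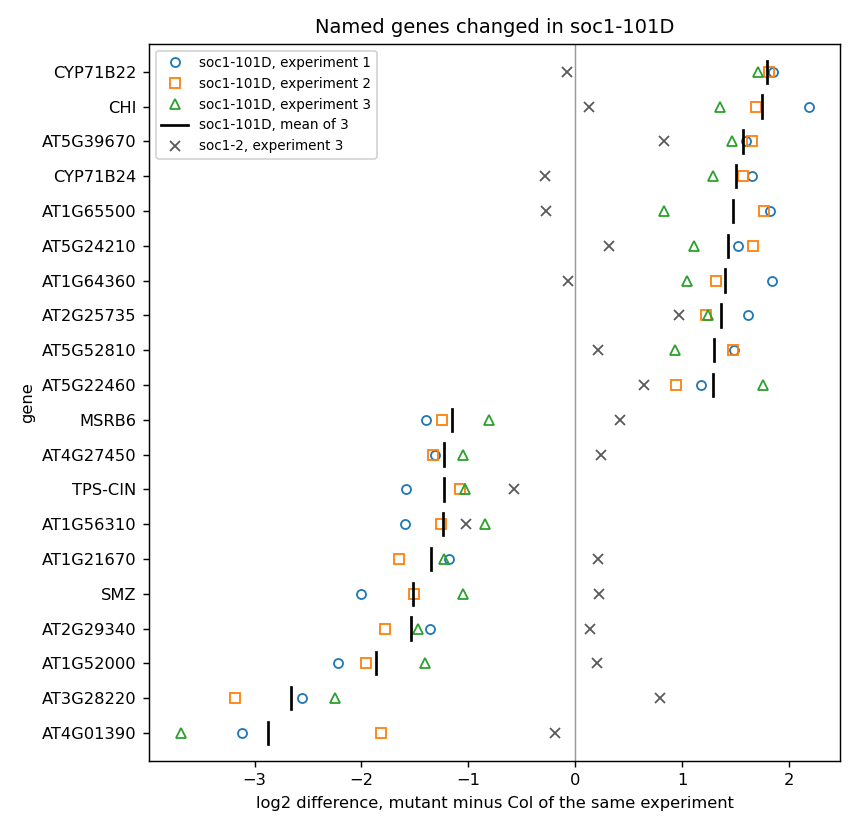
Log2 differences from Col of the same experiment (x axis) for the 20 named genes with the largest called change in soc1-101D (y axis), with open symbols for soc1-101D in experiments 1, 2 and 3, a bar for their mean and a cross for soc1-2 in experiment 3. The 3 soc1-101D values of each gene lie on 1 side of 0, from CYP71B22 with a mean of 1.79 to AT4G01390 with a mean of −2.87.

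The widest fitted difference in soc1-101D was in a probe set with no gene name here, 267509_at. Its scaled signal was 2971, 2457 and 2553 in soc1-101D of experiments 1, 2 and 3 and 8.26, 6.59 and 139 in Col (log2 difference 5.79 ± 0.48, limma adjusted p = 0.00655). On the soc1-2 array it was 14.3. The Col signals of experiments 1 and 2 and the soc1-2 signal lie below the pseudocount of 19.3, so the size of the difference depends on the pseudocount. The unnamed probe set 252170_at was 6.10-fold higher in soc1-101D (log2 2.61 ± 0.24). Of the probe sets without a single gene name, 248337_at had a log2 difference of −2.49 ± 0.36, and 246481_s_at, which is paired with several genes, of −2.09 ± 0.16.

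By size alone, 26 probe sets were at least 2-fold higher and 21 at least 2-fold lower in each of the 3 experiments, and 43 of these 47 were also called. With pairs turned round, the other sign patterns of the 3 experiments held 1 probe set in all. The 74 calls rest on the experiment block and on the filter: limma called 0 probe sets without the block (222 at an unadjusted p under 0.05, against 1504 with it) and 0 with no filter on dim probe sets (1714 unadjusted). Quantile normalization gave 19 calls, and the count was 26 without experiment 1 and 129 without experiment 3. Of the 20 named genes given above, 7 passed with quantile normalization and 6 without experiment 1.

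The gene lists asked which processes moved in soc1-101D. In the flowering time list, 4 of 12 named members were bright enough to be tested, and 1 of them, SMZ, fell, both over all genes and adjusted over the list alone. The clock and flowering regulator GI had a log2 difference of −0.15 ± 0.17, FY, an RNA-processing factor, of −0.08 ± 0.26, and LD of −0.02 ± 0.16, none past the test. The list as a whole had a mean of −0.44 and a camera adjusted p of 0.182.

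The cold regulon, genes induced by low temperature, had the lowest list mean in soc1-101D, with a log2 difference of −1.30 over its 4 tested members. None of the 4 passed over all genes, and 3 (COR15A, COR15B and COR47) fell adjusted over the list alone. Published work on SOC1 mutants is recalled, with no source consulted, as having drawn cold-responsive genes from such profiles, so the list is not taken as independent evidence of its direction. Camera gave an adjusted p of 0.000966, which was lost with an estimated correlation (adjusted p = 0.371) and with fry (adjusted p = 0.15). The estimate for this list was −0.06, below the preset 0.01, so correlation between its members does not account for the loss under camera. With an estimated correlation, camera takes its p from the 2 residual degrees of freedom of the fit. That form has little power here and in the groups below, so its losses do not decide for or against a list. COR15A, whose product protects chloroplasts during freezing, differed from Col by log2 values of −0.84, −3.02 and −4.86 in experiments 1, 2 and 3 (limma adjusted p = 0.115; over the alternatives from 0.0232 without experiment 1 to 1.00 without the experiment block). COR15B differed by 0.01, −1.49 and −2.14 (limma adjusted p = 0.251; over the alternatives from 0.0407 without experiment 1, with a mean of −1.81, to 1.00 without the experiment block). The dehydrin genes COR47 and LTI30 had mean differences of −0.68 ± 0.19 and −0.40 ± 0.24, and LTI30 was higher than Col in experiment 3 (0.32). Col itself ranged widely: COR15A read 157, 5025 and 3223 on the Col arrays of experiments 1, 2 and 3, and 79.0, 604 and 92.7 on those of soc1-101D.

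**Figure D2:**
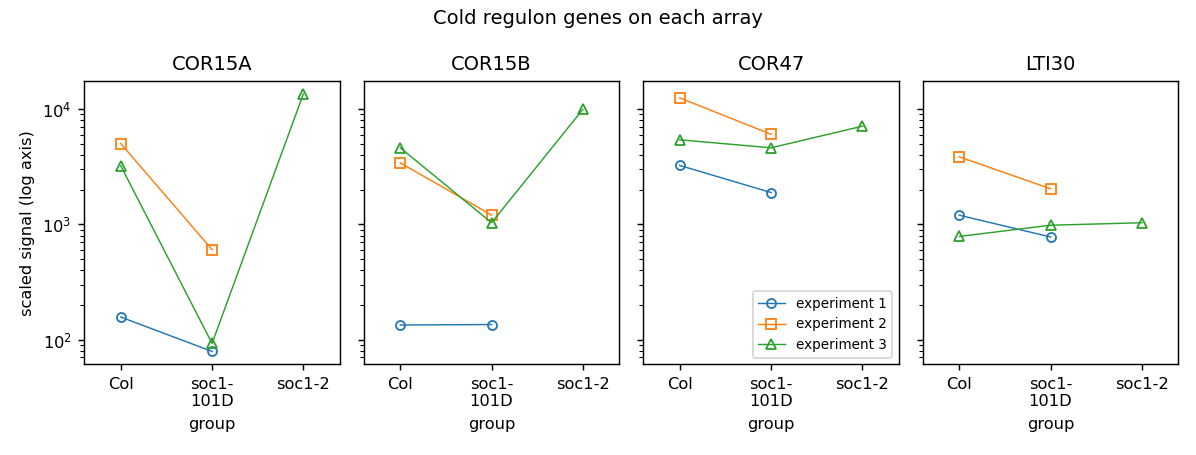
Scaled signal on a log axis (y axis) of COR15A, COR15B, COR47 and LTI30 on each of the 7 arrays by group (x axis), with lines joining arrays of 1 experiment. COR15A was lower in soc1-101D than in Col in all 3 experiments, and its signal on the soc1-2 array was 13552.

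The other tested lists had no member past the test in soc1-101D. The medians were 0.09 for photosynthesis (RCA, LHCB4.1 and LHCB4.2), 0.02 for gibberellin (GID1A, GID1B and AT1G22690) and −0.12 for root markers (PYK10, EXPA7 and EXPA18), with camera adjusted p of 0.423, 0.423 and 0.734. For root markers the mean was −0.06. The 8 tested neighbours of SOC1 had a median of −0.16, at percentile 6.15 of random lists, and a camera adjusted p of 0.423. Of the neighbours, AT2G45670 had a log2 difference of −0.37 ± 0.17 and AT2G45590 one of 0.27 ± 0.14.

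In 4 lists only 1 or 2 members could be tested, and none passed over all genes. GI, already given, stood for the circadian clock, and BCAT4 (log2 −0.17 ± 0.17) for the glucosinolate list. In the anthocyanin list DFR was at 0.16 ± 0.17 and UF3GT at −0.14 ± 0.22. STZ, a zinc finger gene of the touch and handling list, was at 0.44 ± 0.19 (limma adjusted p = 0.449; it rose adjusted over the list alone, where it was the single member). In 8 lists no member was tested: floral meristem and organ identity, abscisic acid and drought, salicylate defence, jasmonate and wounding, heat shock, the cell cycle, the shoot meristem and seed storage.

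The second comparison asked which genes differed when SOC1 was lost. On the soc1-2 array 92 probe sets were at least 2-fold higher and 19 at least 2-fold lower than on the Col array of experiment 3, 37 and 12 of them with 1 gene name. The zinc finger gene STZ was 4.74-fold higher (log2 2.24), and ORA47, an AP2/ERF gene of the jasmonate and wound response, 3.39-fold higher (log2 1.76). COR15A was 4.19-fold higher (log2 2.07). Genes of the TIR-domain immune receptor family AT1G72920, AT1G72940 and AT1G72900 were higher by log2 2.35, 1.65 and 1.63. The other named genes with the largest positive differences were AT4G27280 (2.61), AT2G20670 (2.22), AT3G15450 (1.75) and AT3G46600 (1.66). Some of these soc1-2 signals lay within the range of the Col arrays. AT2G20670 and AT3G15450 read 2081 and 4002, under the 3168 and 6316 of Col in experiment 2. STZ read 1043 against 982 on that Col array, and AT4G27280 2947 against 2170.

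The largest negative difference among named genes was in QQS, an orphan gene that affects starch content, at 4.55-fold lower (log2 −2.19). It read 85.0, against 103, 90.3 and 455 on Col of experiments 1, 2 and 3 and 379 on soc1-101D of experiment 3. The size of this fall thus holds within experiment 3, where the other arrays were high. AT4G14090, an anthocyanin glucosyltransferase gene, was lower by a log2 of −1.65, with a signal of 8.93 on the soc1-2 array, under the pseudocount, and rpoC2, a plastid RNA polymerase gene, by −1.23, where the 68 plastid-encoded probe sets had a median of −0.50. AT2G14255, AT3G09860, AT5G02830 and AT2G31110 had log2 differences of −1.92, −1.57, −1.34 and −1.33, and the soc1-2 signal of AT2G14255, 14.5, also lies under the pseudocount. AT5G05250, AT4G33380 and AT5G26270 were at −1.17, −1.05 and −1.03. The soc1-2 signals of AT5G02830 and AT5G05250, 299 and 313, lay within the range of the Col arrays.

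With a single soc1-2 array these differences have no replicate check of their own. In the limma fit, with spread taken from the other pairs, 0 probe sets passed (387 at an unadjusted p under 0.05, where 682 are expected with no change; smallest adjusted p 0.124), and without experiment 2 the count was 26. On simulated data this comparison recovered 4% of 2-fold changes and 86% of 4-fold changes.

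Of the 6 lists with at least 3 tested members, the cold regulon stood highest on the soc1-2 array, with a mean difference of 0.99 and a median of 0.75, above the medians of all 10000 random lists. Its members differed by 2.07 (COR15A), 1.11 (COR15B), 0.39 (COR47) and 0.39 (LTI30), and 2 rose in the fit adjusted over the list alone, against 0 over all genes. The tests use the fitted coefficients, which were 3.04, 1.57, 0.16 and 0.03 in the same order, with a mean of 1.2, so COR47 and LTI30 were near 0 in the fit. The coefficients also draw on the soc1-101D array of experiment 3. The low COR15A and COR15B there (−4.86 and −2.14 against Col) raise their soc1-2 coefficients above the plain differences. The list result in soc1-2 is therefore not separate from the fall in soc1-101D. The reservation on this list given for soc1-101D holds here too. Camera gave an adjusted p of 0.00593, lost with an estimated correlation (adjusted p = 0.474), with fry (adjusted p = 0.766) and without the experiment block (adjusted p = 0.405). STZ rose adjusted over its 1-gene list alone. The medians of the flowering time, photosynthesis, gibberellin, root marker and SOC1 neighbour lists were 0.10, −0.02, −0.00081, 0.20 and −0.12, with camera adjusted p of at least 0.601. For flowering time the mean was −0.02, and LD was at −0.73.

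The third comparison asked whether genes moved in opposite directions in the 2 mutants, as targets of SOC1 might. Among the 74 probe sets called in soc1-101D, 36 had the opposite sign on the soc1-2 array. Simulations that kept their fitted soc1-101D differences and left soc1-2 unchanged gave 36.6 (28.5 to 43 in 95% of 100 simulations). Such a count lies near an even split by design. The simulation did not repeat the choice of the calls, so it does not show what the shared Col array gives among called probe sets. Of the 37 that rose in soc1-101D, 15 were lower in soc1-2, and of the 37 that fell, 21 were higher. Probe sets at least 2-fold changed in every soc1-101D experiment and at least 2-fold changed on the soc1-2 array numbered 4 with opposite and 2 with the same direction. At 1.5-fold the numbers were 12 and 13. Among the called named genes, some moved the same way in both mutants. These included AT1G56310 (−1.23 in soc1-101D, −1.02 in soc1-2), AT2G25735 (1.36, 0.97), AT5G39670 (1.57, 0.83) and TPS-CIN (−1.23, −0.57).

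Across probe sets the 2 differences correlated at r = 0.05, where the shared Col array of experiment 3 gave r = 0.29 in simulation. The covariance was 0.00426 against 0.0152 simulated, a difference of −0.011. With soc1-101D taken from experiments 1 and 2, so that no array was shared, r was −0.09 against a simulated 0.0013, and 76 of 129 called probe sets had opposite signs. Probe sets are not independent replicates. Each overlap of the 37 risen or 37 fallen probe sets with those 2-fold higher or lower in soc1-2 held 2 probe sets, in opposite and same directions alike. The overlap that the shared Col array alone would give was not estimated.

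Named genes with the largest opposite differences were mostly lower in soc1-101D and higher in soc1-2. After COR15A came AT3G28220 (−2.66 in soc1-101D, 0.80 in soc1-2), AT1G34510 (−0.88, 0.77), AT3G07350 (−0.77, 1.08) and HIS1-3, a linker histone gene (−1.22, 0.73). SAG29, a sugar transporter gene linked to senescence, was at −1.09 and 0.72, AT2G37870 at −0.94 and 0.71, and AT5G11070 at −0.69 and 0.70. AT3G55710 (1.23, −0.79) and SOL1 (0.73, −0.67) went the other way. Except for COR15A, AT5G11070 and SOL1, the soc1-2 signals of these genes lay within the range of the 3 Col arrays. Their soc1-2 differences thus hold against the Col array of experiment 3 and not against every Col array. The means of AT3G55710, AT1G34510 and HIS1-3 rest largely on experiment 2, where the differences were 3.22, −2.03 and −2.25. Without it they were 0.24, −0.31 and −0.70, and the Col signal of AT3G55710 in that experiment, 8.00, lies under the pseudocount. AT3G07350 was at −0.47 without experiment 2, AT5G11070 at −0.36 without experiment 1 and COR15A at −1.93 without experiment 3. Of these 10, AT3G28220 and SAG29 passed in soc1-101D (limma adjusted p = 0.00592 and 0.0408). HIS1-3 passed in 1 alternative, without experiment 3 (−1.75, adjusted p = 0.0232, range over the alternatives 0.0232 to 1.00). SAG29 did not pass without any 1 of the experiments (0.0742, 0.0653 and 0.103 without experiments 1, 2 and 3), under either other scaling or with either other pseudocount (range over the alternatives 0.0408 to 1.00), and its soc1-101D signal of experiment 3, 6.90, lies under the pseudocount.

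**Figure D3:**
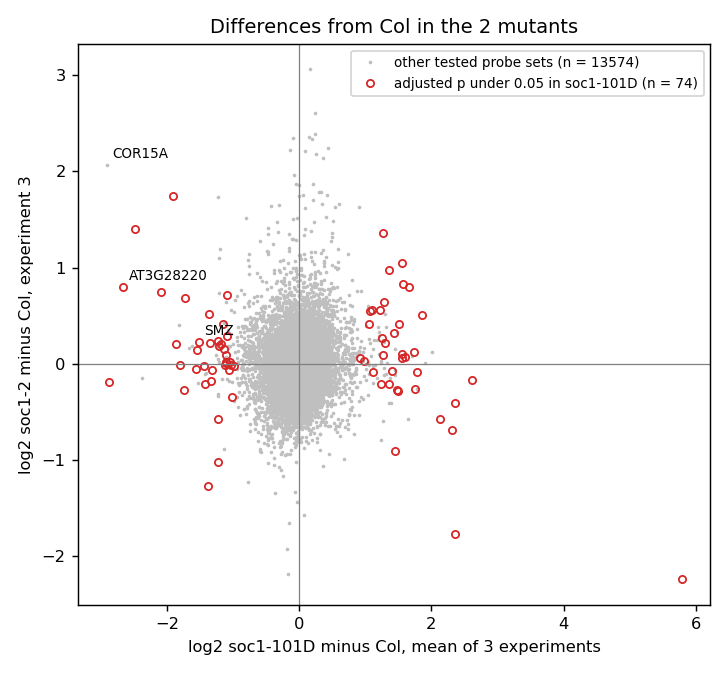
Log2 difference from Col in soc1-101D (x axis, mean of 3 experiments) against soc1-2 (y axis, experiment 3) for 13648 probe sets, with red circles for the 74 called in soc1-101D and the rest as grey points. The called probe sets lie on both sides of 0 in soc1-2, and 36 of them have opposite signs in the mutants.

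The direct comparison of soc1-101D with soc1-2 asked where the mutants differed from each other. Limma called 7 probe sets, 3 higher and 4 lower in soc1-101D, of which 1 had a single gene name. AT3G28220 was lower in soc1-101D by a log2 of −3.25 (limma adjusted p = 0.0245). The 6 without a single gene name had limma adjusted p between 0.00459 and 0.0357, and in 5 of them the 2 mutants differed from Col with opposite signs, which this contrast favours. In the other one the difference came from soc1-2, at 3.06 against 0.17 in soc1-101D. Without the experiment block, and with no filter on dim probe sets, 0 probe sets were called, and without experiment 2 there were 55.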

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

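The rule that picked these results was set in advance, and no test here was chosen after the result was seen. The difference from Col was compared between the 2 mutants by the direct limma contrast, and 7 probe sets differed. The single named gene among them was AT3G28220, with a log2 of −3.25 for soc1-101D minus soc1-2. It was lower than Col in 3 of 3 soc1-101D experiments (−2.56, −3.18 and −2.25) and higher on the soc1-2 array (0.80, with no replicate). Its soc1-2 signal of 761 was above Col of experiment 3 (430) and under Col of experiments 1 and 2 (3463 and 3283). No group held 4 or more arrays, so single arrays were not tested against their own group.

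In the comparison of soc1-101D with Col, 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many calls as the 74 observed, and the highest other split gave 0. Because the arrays are paired, the 3 other splits that part every pair are the ones to compare, and these gave at most 0. The remaining 6 splits part 1 pair and hold the differences between experiments. With 10 splits, a share under 0.05 cannot be reached.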

How the results depend on the processing

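The adjusted p under 0.2 in soc1-2 and the 2-fold rule with 1 experiment left out were chosen after seeing the data. All 20 named genes of soc1-101D against Col kept their sign under every alternative that kept them, but not their call: 7 passed with quantile normalization, 6 without experiment 1, 13 with no pseudocount and 0 with no block or no filter. Of the 73 genes named by rule, 17 changed sign under an alternative, none of them among the 21 called. The pairing decided the counts: with no replicate block, calls went from 74 to 0 for soc1-101D against Col, and from 7 to 0 for soc1-101D against soc1-2, and list calls went from 2 (the cold regulon in each mutant) to 1. With experiment as a random effect soc1-101D had 114 calls, 68 of them among the 74.

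With no filter, both counts were 0 and the 2-fold count went from 47 to 76. The variance prior then had 2.66 degrees of freedom against 5.62, and the smallest adjusted p was 0.456. With the lowest 60% left out (9099 tested) soc1-101D had 152 calls, soc1-2 7 (from 0), the direct contrast 30, opposite signs 73 and the 2-fold rule 30. In the same order, a pseudocount of 0.5 times the common median gave 175, 14, 33, 82 and 27, and a variance trend with a robust prior gave 160, 7, 30 and 77. Quantile normalization gave 19 calls for soc1-101D, 1 for the direct contrast and 14 of opposite sign. Opposite signs are counted among the calls, so they rise with them and are 0 where there are none. No pseudocount gave 37 for soc1-101D, and the deposited scaling 3 for the direct contrast. Where no cause is given, the cause was not tested.

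Leaving out 1 experiment gave 26 (without experiment 1) to 129 calls for soc1-101D, 0 to 26 for soc1-2, 13 to 55 for the direct contrast, 19 to 45 of opposite sign, 1 to 3 list calls and 61 to 137 by the 2-fold rule in the remaining 2. Without experiment 3 no soc1-2 comparison could be made. At an adjusted p under 0.1 soc1-101D had 156 calls and under 0.2 soc1-2 had 17, while the 2-fold rule gave soc1-2 111. At 1.5-fold in every experiment 160 probe sets passed, against 13 in the other sign patterns, and opposite changes in both mutants went from 4 to 12 and those in the same direction from 2 to 13. Opposite signs numbered 76 with soc1-101D from experiments 1 and 2. List calls fell to 0 with an estimated correlation and to 0 with fry. They numbered 3 with quantile normalization and 3 without experiment 1. With no filter they numbered 2, where the cold regulon passed in soc1-101D alone. A list other than the cold regulon thus passed in each of these settings, and which one was not recorded. In soc1-2, the cold regulon also lost its call with no filter (adjusted p = 0.0777, range over the alternatives 0.000238 to 0.766).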

Other observations

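The grouping by symbol prefix and the tests on the soc1-2 set, on the signal of COR15A and COR15B, on the Col array of experiment 3 and on a shared plastid loss were chosen after the results had been seen. Of 15 groups of genes with a shared symbol prefix or a plastid origin, the CYP71 cytochrome P450 family stood out upward in soc1-101D. CYP71B22, CYP71B23 and CYP71B24, which lie close together on 1 chromosome in TAIR10.1, rose by log2 1.79, 1.26 and 1.5, and the soc1-2 array gave −0.08, 0.09 and −0.28. The 10 tested members had a median of 0.17 (0.20 under the deposited scaling and under quantile normalization) and a camera adjusted p of 4.29e-05, which was lost with an estimated correlation (adjusted p = 0.627). Cross-hybridisation between the CYP71B copies could not be decided, since the 7 other members had a median of 0.16 ± 0.06 (SE). By experiment the medians of these 7 were −0.18, 0.14 and 0.23, and none of them was called. The rise of the family therefore rests mainly on the 3 neighbouring genes.

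Other floral repressor genes of the flowering time list were too dim to be tested, and are given here because of their values. AGL18 was lower than Col in soc1-101D in all 3 experiments (−1.37, −0.55 and −1.61), with a signal of 134 ± 31.0 in Col and 48.2 ± 11.8 in soc1-101D (SD, 3 arrays each). SNZ, a close relative of SMZ, differed by −0.30, −0.69 and −1.23. On the soc1-2 array their differences were −0.06 and −0.33. The hypothesis that the gain-of-function allele activated genes near its insertion was tested on the 8 neighbours of SOC1, whose median of −0.16 lay below the upper bound of 0.12 for random lists. A rise of a single neighbour is not excluded by a median.

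The 92 probe sets that were 2-fold higher on the soc1-2 array, STZ, ORA47 and COR15A among them, had medians of 0.01, −0.18 and 0.43 in soc1-101D minus Col of experiments 1, 2 and 3. A candidate explanation is a state of the sample, such as handling or stress, that varied between arrays apart from genotype. The mean of the experiment 1 difference minus the experiment 2 difference over this set was 0.47, outside the −0.17 to 0.06 of random sets matched on signal. This met the prediction for such a state. The random sets were not matched on variability, though, and a set chosen for large change may lie outside them for other reasons, so the test does not decide. The means of the 2 differences, 0.056 and −0.41, also lay further apart than the medians. Loss of SOC1 function stays open as a cause, because there was 1 soc1-2 array. The highest median, 0.43, comes from experiment 3, whose Col array also entered the choice of the set, so it excludes nothing. The medians of 0.01 and −0.18 did not decide on a response opposed in the 2 mutants.

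COR15A and COR15B were furthest below Col in soc1-101D in experiments 2 and 3, where Col was high. In experiment 1, where the fall was smallest, the highest signal of the 2 genes was 157, under the common median of 193 and above the pseudocount of 19.3, so signal near the floor was neither shown nor excluded as the reason for the small differences there. Less of the state, of unknown nature, that marks the set higher on the soc1-2 array may be a cause: without the cold list, the medians of that set were 0.037 ± 0.12 in experiment 1 and −0.17 ± 0.09 in experiment 2 (SE over 90 probe sets), so neither lay 2 SE from 0 and the test did not decide. In experiment 3 the median was 0.44, but a set chosen against the Col array of experiment 3 is raised there by construction, so that value was not used although the prediction was first written for all 3. An effect of SOC1 on these genes stays open and untested here.

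The 68 plastid-encoded probe sets were lower than Col by medians of −0.51, 0.054 and −0.52 in soc1-101D of experiments 1, 2 and 3 and −0.50 in soc1-2, except for the small positive value in experiment 2, with the same signs under the deposited scaling and quantile normalization. Camera gave an adjusted p of 2.05e-08 in soc1-101D, lost with an estimated correlation (adjusted p = 0.785). The Col array of experiment 3 cannot have caused the −0.51 of experiment 1, which does not use it. There 66 of 68 probe sets were below 0, in 1 pair of arrays. That value was less than 2 of the SD between Col arrays given below. The SD also holds differences between experiments, which pairing removes, so this bound does not decide. The prediction was first written with the SE over probe sets (0.045), which −0.51 would have passed. For experiment 3 and soc1-2 that Col array was not excluded, but it would have to be high. The set's mean log2 signal on it was 11.2, against 11.8 and 10.9 on Col of experiments 1 and 2 (−0.16 from their mean). Preparation or labelling that varied between arrays is consistent with the SD of 0.45 between the 3 Col arrays in the set's mean log2 signal, above the upper bound of 0.20 for random sets matched on signal, though growth of the seedlings could give the same spread. A loss shared by both mutants could not be told apart from it. The highest median, 0.054, lies well within that SD, but the SD also holds differences between experiments, which the pairing removes.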
